A study of Mus musculus with 181 samples.

How the data were processed

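RNA-seq libraries were made by Smart-seq2 from 1000 double-sorted splenic T cells each, per the labels' protocols. Reads were aligned to mm10 with STAR 2.7.3a and counted with featureCounts, per the submitters' processing notes, and the authors deposited raw counts per gene symbol. The annotation release and strand setting are not given in the sources used here. The table holds 55011 genes in 181 columns, each matched to a sample, and 3261 genes have no count in any library. Groups were taken from the labels (sex, line, genetic background, fraction or gate). Of the 181 libraries 178 were placed and 3 were left out because title and labels disagree. The labels do not state that each library of a group is a separate animal. Libraries were treated as independent replicates, although WT aTreg, reTreg and Tconv libraries share mice by label.

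Groups were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (glmQLFit, robust, and glmQLFTest) after filterByExpr with a minimum count of 10 and TMM scaling. Standard errors are the log2 fold change divided by the square root of F. Adjusted p-values follow Benjamini-Hochberg within each comparison, with a threshold of 0.05. All aTreg groups entered one fit, as did all reTreg groups and all gates, and the WT and Tconv comparisons had fits of their own. Each line was set against WT of its own sex, background and fraction. The mean over lines covered 8 lines in males and 6 in females (without 327fs), and the sex difference the 6 lines carried by both. Female R51Q was compared on the GFP background. Counts were read as CPM for levels, and log2 CPM with a prior count of 3 for lists.

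For 20 gene lists (259 genes, 3 of them absent from the table) written before the data were examined, camera of limma 3.58.1 was run with a preset correlation of 0.01, and again with an estimated correlation; fry was run beside it. The lists are Treg identity, naive and resting T cell, effector Treg, helper cytokines, Th1, Th2, Th17, Tfh, type I interferon response, cell cycle, TCR early response, NF-kB targets, IL-2 and STAT5 targets, glycolysis, oxidative phosphorylation, ribosomal proteins, B cell markers, myeloid markers, CD8 and NK markers, and erythroid and platelet markers. Counts of members are given over all genes tested and, where stated, adjusted over the list alone.

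Named genes were chosen by a rule fixed before the data were examined, as were the groups, tests and alternatives unless stated. In the means, the sex differences, WT Treg against Tconv and female WT aTreg against reTreg these are the 10 largest rises and falls, and in single lines and gates the 3 largest, among genes with an adjusted p under 0.05 and a mean of at least 10 CPM, in the means with the same sign in all lines but 1. Predicted genes, pseudogenes and immunoglobulin and TCR segments were left out, and for sex differences Xist, Tsix and Y-linked genes. Foxp3, Il2ra, Ctla4 and Ikzf2 are always covered, and up to 4 members per list. Where a group had no counts of a gene, the fold is a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its counting interval. Intervals and floors cover counting error only. Genes with near-identical copies (Gbp2b, Lilr4b, Oas1a, Slc28a2b, Dnah7a, Ifit3b, Apol7e and the Ly6 family) are uncertain, since reads could be split between copies.

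Library blocks were defined from the form of the sample titles after the data were seen: titles with the fraction before the line (block 1, 84 libraries), with the line before the fraction (block 2, 27), male numbers from 4 up in that form (block 3, 12) and titles with a number sign (block 4, 26). The median number of genes detected was 22002, 22279, 24608.5 and 29576, and the median share of mitochondrial counts 1.10%, 1.90%, 1.52% and 0.855%. The gates (30) and 2 other libraries stood apart. Alternatives were DESeq2 1.42.0, RLE scaling, no gene filter, a filter at 5 CPM, WT pooled over backgrounds, littermate WT alone, no background term, other choices for female R51Q, low-quality libraries left out, title format as a covariate, the mouse label or the title number as a replicate block, and each library of groups of 2 to 5 left out. Added after seeing the data were the library block as a covariate, block 3 left out, the R337Q line left out and the mouse as a replicate block in male WT Treg against Tconv. Refits with a library left out or other splits kept the gene set and the dispersion trend, with the quasi-likelihood dispersion estimated again, and a lone library was assumed to vary like the other groups.

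WT titles name the mouse, and aTreg and reTreg of the same mouse deviated together, with correlations of 0.196 to 0.440 over 6 male and 0.115 to 0.739 over 12 female pairs. With deviations taken within library blocks these ran from -0.00732 to 0.253 in males and from -0.0157 to 0.520 in females, so part was shared by block. The mouse as a replicate block moved neither count by more than 1.5 times. Libraries of male Lys199del and WT with the same title number deviated together too, with correlations of 0.200 to 0.346 over 6 aTreg and 0.132 to 0.457 over 4 reTreg pairs, and the labels do not say what the number means. Those deviations were not taken within library blocks, which the numbers largely follow there. Among 236 pairs of libraries of a group none were identical, and the lowest chi-square per degree of freedom was 4.02. The tests were tested on simulated data with 200 changed genes, drawn for each pair of groups alone and without differences between library blocks. For male R337Q aTreg 181 genes were called, 12 of them unchanged, for male R51Q aTreg 137 with 8 and for female 327fs CD25lo cells 150 with 4, and a raised cell cycle list ranked first with no other list called. The remaining calls were changed genes or members of that list. These numbers do not describe comparisons that part the blocks. Falls beyond that of Foxp3 were tested with limma on log2 CPM minus that of Foxp3 in each library, with Holm's adjustment. For shared WT libraries, unchanged groups were simulated 20 times.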

Results

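RNA was measured by RNA-seq in splenic CD4 T cells of mice that carry mutations of Foxp3, the X-linked gene of the transcription factor that specifies regulatory T cells (Treg). The series asks how mutations found in patients with the immune disorder IPEX compare in their effects in mice. Not every line need carry such a change. The titles mark 327fs as a knockout and do not number N354A and del176-181 by residue as they do the other lines. There were 181 libraries of 1000 sorted cells each, of which 178 fell into groups by their labels and 3 had labels that disagreed. Treg were sorted as CD25-positive cells and are labelled aTreg and reTreg, taken here as the field's shorthand for activated and resting Treg. By label, 73 libraries held aTreg, 65 held reTreg and 13 held CD25-negative conventional T cells (Tconv). The other 30 came from gates on GFP and CD25 in mice of the 327fs frameshift line and their wild-type (WT) littermates. The total count per library ran from 849954 to 9997700, with a median of 3897146. It ran from 2253446 to 9997700 in aTreg, from 849954 to 7861401 in reTreg, from 3018030 to 7109516 in Tconv and from 2607525 to 6695353 in the gates.

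Hemizygous males carried R51Q, C168Y, del176-181, Lys199del, R309Q, F324L, R337Q or N354A. Heterozygous females carried R51Q, C168Y, Lys199del, R309Q, F324L, R337Q or 327fs. Groups of a mutant line held 2 to 5 aTreg and 2 to 4 reTreg libraries. WT libraries came from 2 genetic backgrounds, B6 and B6 with a GFP reporter in Foxp3, and each line was compared with WT of its own sex, background and fraction. The WT groups held 9 female B6, 5 female GFP, 3 male B6 and 6 male GFP aTreg libraries, and 7, 5, 2 and 4 reTreg libraries in the same order. Fold changes are log2 values ± standard error (SE), and levels are counts scaled to TMM-adjusted library totals (CPM) ± SD. Single-library levels of Ddx3y, Xist, Trac, Cd4, Cd3e and S100a8 are CPM over raw library totals. So are levels of Foxp3 in the 3 libraries whose labels disagreed. The p-values are Benjamini-Hochberg adjusted p-values of edgeR's quasi-likelihood test unless another test is named. The libraries fall into blocks by the form of their sample titles, so counts of genes are also given with the library block as a covariate wherever that moved them by more than 1.5 times.

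Male WT Treg were set against male WT Tconv (15 against 5 libraries) as a reference for what separates these lineages. By label the 15 Treg libraries came from 9 mice, and 4 of the 5 Tconv libraries came from the same mice. Foxp3 stood at 1228 ± 517 CPM in Treg and 64.5 ± 71.5 CPM in Tconv, a rise of 4.12 ± 0.54 (adjusted p = 9.27e-06). All 23 measured members of the Treg identity list rose, among them Il2ra, the alpha chain of the IL-2 receptor (4.76 ± 0.45), the inhibitory receptor Ctla4 (3.86 ± 0.18), the transcription factor Ikzf2 (3.89 ± 0.28) and Lrrc32, which anchors latent TGF-beta (5.11 ± 0.73). Treg and Tconv were sorted by CD25, the product of Il2ra, so its rise was partly set by the sort. Levels of Il2ra in aTreg and reTreg of the lines come from the same sort. Of 15 genes of naive and resting T cells 13 fell, including the phosphodiesterase Pde3b (-4.29 ± 0.43) and Igfbp4 (-4.24 ± 0.21), and 1 rose. Ceacam15 rose by 6.08 ± 0.64 and Pdlim4 fell by 6.16 ± 0.46. The decoy receptor Il1r2 was close to the floor in Tconv, and its ratio was 190 with a counting interval of 64.8 to 921. Of the other lists, 16 of 23 effector Treg genes, 9 of 11 NF-kB targets, 6 of 9 IL-2 and STAT5 targets and 4 of 4 measured Th2 genes rose, while 5 of 10 Th1 genes fell. Ribosomal protein genes fell as a list (13 of 20 lower), with an adjusted p of 0.0838 with an estimated correlation. In all 1627 of 12809 genes differed, 943 higher and 684 lower in Treg, and 2490 without library block 3. With the mouse as a replicate block 1627 genes passed as well (890 higher, 737 lower), of which 1284 were shared.

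Within WT females, 14 aTreg were compared with 12 reTreg libraries of the same mice to define the activated state. The inhibitory receptors Pvrig (6.00 ± 0.51), Klrg1 (4.69 ± 0.76) and Tigit (4.30 ± 0.56), the cytokine Il10 (4.38 ± 0.61) and the chemokine receptor Cxcr6 (4.18 ± 0.41) rose in aTreg. The homing receptor Sell stood at 262 ± 82.4 CPM in aTreg and 1706 ± 318 CPM in reTreg (adjusted p = 1.37e-13), Ly6c1 fell by 4.51 ± 0.19 and the chromatin organiser Satb1 by 2.69 ± 0.13. Of 23 effector Treg genes 22 rose, as did 6 of 7 Tfh and 6 of 8 Th1 genes, while 13 of 15 naive and resting genes and 7 of 9 IL-2 and STAT5 targets fell. Il2ra fell by 0.80 ± 0.10, Ctla4 rose by 1.04 ± 0.15 and Ikzf2 rose by 0.75 ± 0.17. Foxp3 stood at 1287 ± 277 CPM in aTreg and 1470 ± 362 CPM in reTreg (-0.21 ± 0.13, adjusted p = 0.248). In male WT it was called lower in aTreg only with the library block (-0.30 ± 0.09, adjusted p = 0.0305, against -0.15 ± 0.21 and 0.759 without). The cell cycle list was higher (7 of 15 members, adjusted p = 0.162 with an estimated correlation) and all 20 ribosomal protein genes were lower (adjusted p = 0.0724 with an estimated correlation). The comparison called 2823 of 12497 genes, and the male one (9 against 6 libraries) called 1379 of 12027 genes, or 2227 without library block 3.

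Foxp3, the mutated gene, lies on chromosome X at 7573644 to 7595245 on the plus strand of mm10. Its RNA differed from WT in 3 of the 30 comparisons of a line with WT. In female 327fs it stood at 291 ± 37.8 CPM in aTreg (n = 3), against 1098 ± 138 CPM in WT of the GFP background (n = 5), a fall of 1.91 ± 0.26 (adjusted p = 6.97e-08). In 327fs reTreg it stood at 402 ± 7.93 CPM (n = 3) against 1297 ± 162 CPM (n = 5), a fall of 1.69 ± 0.27 (adjusted p = 2.12e-05). In female R337Q aTreg it stood at 307 ± 83.9 CPM (n = 2) against 1411 ± 258 CPM in WT of the B6 background (n = 9), a fall of 2.20 ± 0.30 (adjusted p = 2.23e-07). The same line's reTreg had 1905 ± 654 CPM (n = 2) against 1499 ± 423 CPM (n = 7), and male R337Q aTreg had 1597 ± 63.4 CPM against 1859 ± 216 CPM (n = 3 each), neither of which passed the test. For R337Q aTreg the male minus female effect on Foxp3 was 1.98 ± 0.38 (adjusted p = 0.00159). Male WT aTreg stood at 1859 ± 216 CPM on B6 and 876 ± 326 CPM on the GFP background, where 2 of the 6 libraries belong to library block 3. Female R51Q libraries of the B6 background are outside the 30 comparisons. They had 806 ± 71.9 CPM of Foxp3 in aTreg and 654 ± 31.8 CPM in reTreg (n = 2 each). Each lay below the lowest female WT library of that background (959 CPM in aTreg and 743 CPM in reTreg).

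**Figure D1:**
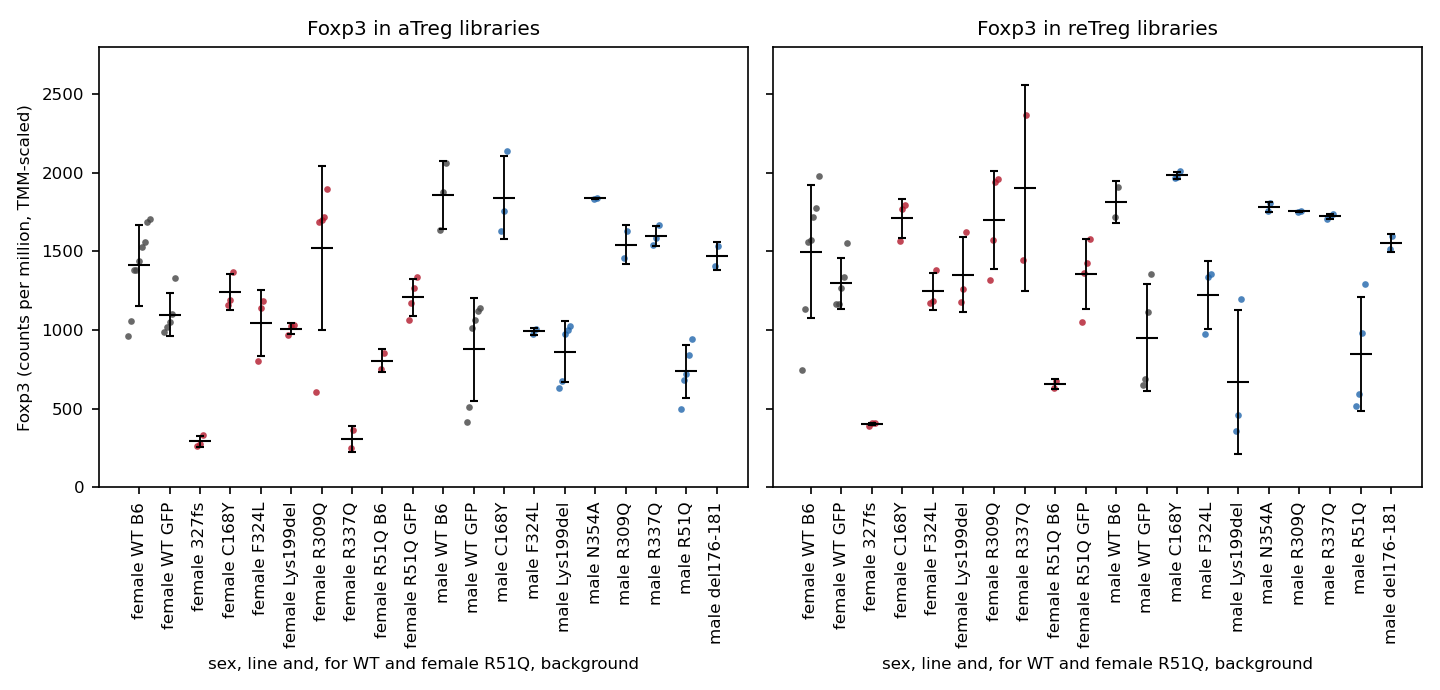
Foxp3 in CPM for every aTreg (left) and reTreg (right) library, grouped by sex and line. Each point is a library, horizontal bars are means and vertical bars are 1 SD. Female 327fs (291 and 402 CPM), female R337Q aTreg (307 CPM) and female R51Q of the B6 background (806 and 654 CPM) lie below their WT groups.

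In the heterozygous 327fs females, whose frameshift is taken to remove functional protein from cells that use the mutant X chromosome, most Treg identity genes were lower in both fractions. In aTreg 19 of 23 Treg identity genes fell and 1 rose, among them Il2ra, at 240 ± 25.4 CPM against 480.0 ± 136 CPM in WT (adjusted p = 0.000442), and Ikzf2 (-1.57 ± 0.26). Of the effector Treg list 14 of 23 fell, and 10 of 15 naive and resting genes rose. Klrg1 had no counts in the 3 mutant libraries and was at least 1073-fold lower, the metalloproteinase Mmp9 at least 96.5-fold and the transporter Slc7a10 at least 61.4-fold. The kinase adaptor Prr5l rose by 4.44 ± 0.77, the desmosomal gene Dsp by 4.59 ± 1.20 and the collagen gene Col3a1 by 6.19 ± 1.22, the last at 56.2 ± 95.6 CPM. Helper cytokine (3 of 8) and Th17 (2 of 5) genes rose, and B cell markers (3 of 10), early TCR response genes (3 of 17) and NF-kB targets (3 of 11) fell, all as lists that also passed with an estimated correlation. In reTreg 18 of 23 Treg identity genes, 4 of 23 effector Treg genes and 5 of 9 IL-2 and STAT5 targets fell and 5 of 15 naive and resting genes rose, with Il2ra at -1.72 ± 0.18, Ctla4 at -1.66 ± 0.26 and Ikzf2 at -1.07 ± 0.23. The gamma-glutamyltransferase Ggt5 (5.51 ± 0.89), Il1rl2 (3.83 ± 0.84) and Pde3b (3.62 ± 0.74) rose in reTreg, and Dgat2 fell by 4.67 ± 0.81. The ratio of WT to mutant was 162 for Lamc1 (counting interval 28.9 to 6418) and 105 for Ceacam15 (29.1 to 873). In aTreg 646 of 18280 genes passed, 233 higher and 413 lower, and in reTreg 294 of 18055, 96 higher and 198 lower. Without 327fs replicate 2 the aTreg count was 378, without replicates 1, 2 or 3 the reTreg count was 173, 177 or 170, and with littermate WT alone the counts were 302 and 111.

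R337Q, a substitution in the DNA-binding forkhead domain, gave more genes in female aTreg than any other substitution. In female aTreg (2 against 9 libraries) the median total count was 0.660 of that of WT, and replicate 2 had the lowest total (2253446) and the fewest genes detected (18856) of all aTreg libraries, with 2.39% mitochondrial counts. There 17 of 23 Treg identity genes fell, with Ctla4 at -2.40 ± 0.27 (adjusted p = 1.12e-09), Il2ra at -1.16 ± 0.23 and Ikzf2 at -1.05 ± 0.28. Of the effector Treg list 12 fell and 1 rose. The lipoxygenase Alox8 was at least 63.3-fold lower, Cep112 at least 43.4-fold and Ankrd55 at least 29.7-fold. Cxcr6 rose by 2.53 ± 0.56, Atp8a2 by 2.60 ± 0.64 and Zbtb16, a transcription factor of innate-like T cells, by 3.51 ± 1.02. Cell cycle (5 of 15), Th1 (3 of 10) and helper cytokine (2 of 8) genes rose as lists, IL-2 and STAT5 targets (3 of 9) and Th2 genes (2 of 6, with 1 higher) fell, and markers of CD8 T and NK cells were higher as a list with no single member called. In female reTreg (2 against 7) replicate 1 was of low quality, with 849954 counts and 2.97% mitochondrial counts. There 3 Treg identity genes fell and the erythroid and platelet markers were higher as a list (adjusted p = 0.0296 with an estimated correlation). Ccr6 fell by 4.58 ± 1.07, the receptor Gpr34 by 2.21 ± 0.38 and the syndecan Sdc4 by 2.17 ± 0.41, while Vipr1 (2.30 ± 0.55), Tdrp (1.79 ± 0.35) and Sema4a (1.75 ± 0.33) rose, of which Ccr6, Sdc4, Vipr1 and Tdrp lost their call with low-quality libraries left out, where 20 genes passed. The test called 797 aTreg genes (295 higher, 502 lower) and 50 reTreg genes (19 higher, 31 lower). With the library block these were 1326 and 130, of which 710 of the 797 aTreg genes were shared, and Il2ra (-0.64) and Ctla4 (-1.17) in reTreg passed as well. A single mutant library left aTreg with 214 or 181 genes (without replicate 1 or 2) and reTreg with 14 or 0 (without replicate 1 or 3).

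In hemizygous R337Q males the Foxp3 level was close to WT, and the genes that changed were fewer. In aTreg (3 against 3) Sdc4 fell by 4.18 ± 0.37 (adjusted p = 6.33e-13), the nucleoside transporter Slc28a2b by 4.10 ± 0.61 and the proton pump subunit Atp6v0d2 by 3.71 ± 0.72. The protease Bace2, without counts in WT, was at least 86.2-fold higher, and the hypoxia-inducible factor Epas1 (5.21 ± 1.14) and Cpne7 (5.10 ± 1.18) rose. In reTreg (3 against 2) Sdc4 (-3.75 ± 0.43), the phosphatase Ptprv (-2.88 ± 0.63) and Slc28a2b (-2.15 ± 0.47) fell, and Igfbp4 (2.41 ± 0.40), the myosin Myo6 (2.30 ± 0.52) and Apol7e (1.95 ± 0.37) rose. Ctla4 in aTreg was at -0.89 ± 0.24 (adjusted p = 0.0569, or 0.00252 with the library block). Helper cytokines in aTreg and cell cycle genes in reTreg were higher as lists, also with an estimated correlation (adjusted p = 0.00427 and 0.0141), with no member called. The counts were 103 in aTreg (41 higher, 62 lower) and 27 in reTreg (8 higher, 19 lower), and 167 and 42 with the library block. Leaving out any one library of either group gave 56 to 65 aTreg and 7 to 15 reTreg genes.

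N354A, another forkhead substitution, was available in males only (2 against 3 aTreg libraries, 2 against 2 reTreg). In aTreg the adhesion molecule Vcam1 (5.67 ± 1.24), Il1r2 (3.21 ± 0.76) and the dynein gene Dnah7a (2.83 ± 0.42) rose, and Atp6v0d2 (-4.31 ± 0.91) and Pstpip2 (-3.81 ± 0.92) fell. The WT to mutant ratio of Mmp9 was 94.1 with a counting interval of 25.8 to 780. In reTreg Igfbp4 rose by 2.26 ± 0.42 and Ly6c1 fell by 1.98 ± 0.35. The cell cycle list was higher in reTreg (adjusted p = 0.0148 with an estimated correlation) with no member called. In aTreg 45 genes passed (12 higher, 33 lower), 72 with the library block, and in reTreg 2, or 12 with the block. Without mutant replicate 1 or 2 the aTreg count was 8 or 2, and it was 27 or 26 without WT replicate 1 or 2. In reTreg it was 0 without either mutant library or WT replicate 1, and 1 without WT replicate 2.

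The remaining lines changed fewer genes or gave counts that moved with the library block. In male del176-181 aTreg (2 against 3) Atp6v0d2 (-4.72 ± 0.95), Ptprv (-1.75 ± 0.33) and the stress gene Sesn1 (-1.34 ± 0.24) fell and Dnah7a rose by 2.21 ± 0.42. Myeloid markers, erythroid and platelet markers and cell cycle genes were higher there as lists and naive and resting genes lower, with adjusted p from 0.00873 to 0.0474 with an estimated correlation and no member called. Ptprv (-1.13 ± 0.21) and the kinase Matk (-1.01 ± 0.18) fell in male Lys199del aTreg (5 against 6). In female Lys199del aTreg (3 against 5) Atp6v0d2 (-4.53 ± 0.70), Cep112 (-2.51 ± 0.52) and the peptidase Cpq (-1.92 ± 0.43) fell, and Itm2a (2.48 ± 0.43), Ms4a4c (2.26 ± 0.50) and the signalling inhibitor Spry1 (1.90 ± 0.35) rose. In male Lys199del reTreg (3 against 4) the sugar transporter Slc35d1 (-1.63 ± 0.26), Fam129c (-2.27 ± 0.46) and Mob2 (-1.07 ± 0.22) fell and Taf13 (1.51 ± 0.32), Cox10 (1.43 ± 0.28) and Pdp1 (1.28 ± 0.28) rose, but 0 genes passed there with low-quality libraries (its replicate 4, with 891357 counts) left out. Junb, an AP-1 subunit, rose by 1.36 ± 0.27 in female R309Q aTreg (5 against 9), where the IL-2 and STAT5 targets were higher as a list (adjusted p = 0.0214 with an estimated correlation). In female F324L reTreg (3 against 5) Utp18 (1.90 ± 0.40), Fnta (1.83 ± 0.36) and Ube3a (1.42 ± 0.30) rose, with 8 genes called and 0 with the block. The counts were 5 for male del176-181 aTreg (16 with the block), 2 and 8 for male Lys199del aTreg and reTreg (12 and 73, and 2 each with the title number as a replicate block), 17 for female Lys199del aTreg and 2 for female R309Q aTreg (10). Single libraries moved each of these by more than 1.5 times, from 0 to 4 genes in del176-181, 1 to 5 and 0 to 1593 in male Lys199del aTreg and reTreg, 1 to 68 in female Lys199del, 3 to 31 in female R309Q and 0 to 20 in F324L.

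R51Q, in the amino-terminal repressor region, and C168Y gave many genes whose calls were largely lost with the library block. In male R51Q aTreg (5 against 6) Tgm2 (1.85 ± 0.53), Gpr19 (1.77 ± 0.41) and Klrb1f (1.76 ± 0.48) rose and the replication factor gene Dtl (-1.92 ± 0.50), Unkl (-1.84 ± 0.52) and Fam13b (-1.82 ± 0.45) fell. Of 789 genes (368 higher, 421 lower) 38 stayed called with the block, and of these 6 only Gpr19 did. All 789 kept their direction with the block, with a median share of 0.743 of the fold change left. Without library block 3 the count rose to 3975, 700 of the 789 among them. Ribosomal protein genes were higher as a list (11 of 20, adjusted p = 0.384 with an estimated correlation). Under edgeR's RLE scaling 29.6% of the male R51Q aTreg calls were higher in the mutant and under DESeq2 28.3%, against 46.6% here. In male R51Q reTreg (4 against 4) 160 genes passed (109 higher, 51 lower; 65 with the block, 21 of them shared; median share left 0.691), led by Wdfy1 (-1.74 ± 0.39), Itgb8 (-1.63 ± 0.41), Slc26a6 (-1.50 ± 0.38), Cbarp (2.23 ± 0.53), Apobec1 (1.75 ± 0.46) and Plscr3 (1.47 ± 0.34), and 528 genes passed with the title format as a covariate and 1836 without library block 3, where mutant and WT libraries are of different blocks. The share of higher calls was 68.1%, 52.8% under RLE and 46.9% under DESeq2. Without a single mutant library the counts ran from 21 to 1794 in aTreg and from 2 to 543 in reTreg. Female R51Q (4 against 5) gave 3 reTreg genes, of which Cggbp1 (-1.34 ± 0.27) and Tmem223 (0.99 ± 0.20) are named, 0 with the block, and 0 to 21 without a single mutant library. Cggbp1 reversed its direction with the B6-background libraries alone. In female C168Y reTreg (3 against 7) Arrdc3 (2.59 ± 0.39), the zinc transporter Slc30a4 (2.24 ± 0.44), Rnf168 (1.97 ± 0.51) and Ikzf2 (0.75 ± 0.21) rose and Pstpip2 (-2.54 ± 0.51), Tcf7l2 (-2.10 ± 0.52) and Pfdn4 (-1.87 ± 0.49) fell, among 630 genes (310 higher, 320 lower) of which 0 stayed called and 594 kept their direction with the block (median share left 0.402). Leaving out replicate 1, 2 or 3 gave 125, 162 or 150.

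In female C168Y aTreg (3 against 9) Themis, which tunes TCR signalling (1.46 ± 0.27), and the protease Ctsw (1.32 ± 0.29) rose, and Pstpip2 (-3.18 ± 0.68) and Gsta4 (-2.02 ± 0.42) fell. Treg identity genes were lower and Th1 genes higher as lists (adjusted p = 0.00437 and 0.0156 with an estimated correlation), with 1 Th1 and no Treg identity member called. S100a8 was called higher (8.24 ± 1.01) at 80.8 ± 140 CPM, and without replicate 2 it stood at -0.73. The count was 11 (8 higher, 3 lower), 0 with the block and 1 without replicate 2. No gene passed in 11 comparisons of a line with WT by edgeR's quasi-likelihood test. In aTreg these were male C168Y (444 genes at an unadjusted p under 0.05; 2 by DESeq2), male R309Q (396; 1), male F324L (978; 3), female R51Q (626; 1) and female F324L (812; 1). In reTreg they were male C168Y (381; 1), male del176-181 (317; 3), male R309Q (288; 0), male F324L (1599; 1), female Lys199del (925; 5) and female R309Q (986; 9). In male R309Q aTreg the CD8 and NK markers (adjusted p = 0.0291 with an estimated correlation) and in its reTreg the myeloid markers (0.0300) were higher as lists with no member called. Female R51Q aTreg did have genes called when its B6-background libraries were used instead.

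**Figure D2:**
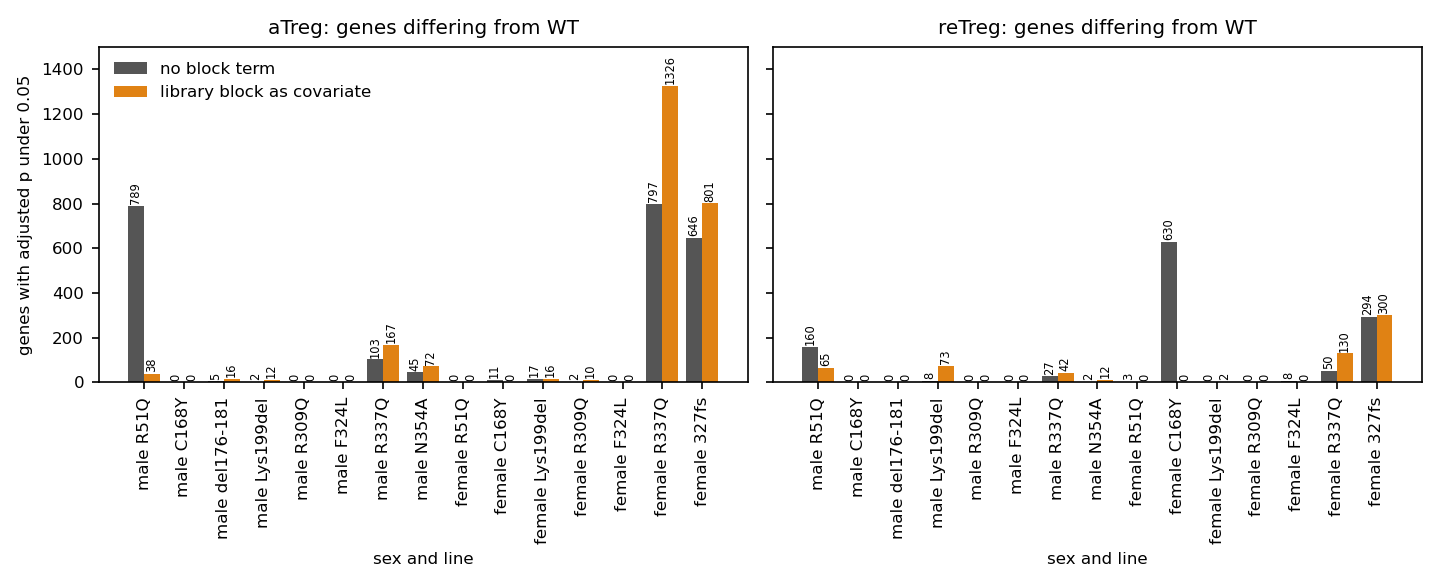
Number of genes with an adjusted p under 0.05 against WT for each sex and line, in aTreg (left) and reTreg (right), without and with the library block as a covariate. R337Q and 327fs females keep high counts with the block (1326 and 801 in aTreg), while male R51Q aTreg drops from 789 to 38 and female C168Y reTreg from 630 to 0.

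The mean over lines asks what the substitutions and in-frame deletions share, and most calls of each mean were lost without the R337Q line. Lines of a background share their WT libraries, so the signs of single lines are not independent. In male aTreg (8 lines, 24 against 9 libraries) the mean fell by 0.94 ± 0.14 for Ptprv (lower in 8 of 8 lines, adjusted p = 0.000124), by 1.06 ± 0.21 for the chemokine receptor Ccr2, by 1.05 ± 0.19 for Sytl2, by 0.98 ± 0.16 for Sdc4, by 0.72 ± 0.17 for Ccr4 and by 0.67 ± 0.14 for the interferon-gamma receptor Ifngr1. Gbp2b, Gpr146, Slc2a3 and Matk also fell, and Dnah7a rose by 1.17 ± 0.23. Without the R337Q line 1 of the 26 genes (2 higher, 24 lower) stayed called, Ptprv (-0.83, adjusted p = 0.00351). Most of the fold was kept there by Ccr2 (-0.97), Sytl2 (-0.81), Ccr4 (-0.59), Ifngr1 (-0.47) and Dnah7a (0.99), while Sdc4 stood at -0.52. Helper cytokines were higher as a list (adjusted p = 0.00687 with an estimated correlation) with no member called. The effector Treg list was lower (1 of 23 members called lower; 4 lower and 1 higher adjusted over the list alone), Th17 genes were lower, and cell cycle, ribosomal protein, myeloid and erythroid and platelet lists were higher, with adjusted p of 0.132, 0.223, 0.475, 0.635, 0.128 and 0.475 with an estimated correlation. The count was 51 with the library block, and 13, 11 or 15 without WT B6 replicate 1, 2 or 3. With littermate WT alone, which some lines lack, no gene passed. The share of higher calls was 7.69%, and 24.4% under DESeq2.

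In female aTreg (6 lines, 20 against 14 libraries) Itgae, the integrin that binds E-cadherin, fell by 0.92 ± 0.14, Klrg1 by 1.05 ± 0.21, Tigit by 0.75 ± 0.12, the effector regulator Prdm1 by 0.80 ± 0.17 and Gpr83 by 0.65 ± 0.13. Ankrd55, Ccr3, the IL-33 receptor Il1rl1, Pard6g, Epcam, H2-Ob, Tcn2 and Ubl3 fell as well, by 0.50 to 1.60. Tnfsf8, the CD30 ligand, rose by 0.85 ± 0.13, and Themis, Ehd3, Mtap and Pa2g4 by 0.44 to 0.66. Treg identity genes were lower as a list (3 of 23 called, 9 adjusted over the list alone), as were effector Treg genes (5 of 23, 10 over the list alone), and helper cytokines and Th1 genes were higher (adjusted p = 0.00203, 0.0178, 0.000526 and 0.00788 with an estimated correlation). Il21 rose by 3.10 ± 0.79. Cell cycle, glycolysis, oxidative phosphorylation and ribosomal protein lists were higher and B cell markers lower, with adjusted p of 0.252, 0.280, 0.444, 0.483 and 0.109 with an estimated correlation. Of 83 genes (7 higher, 76 lower) 0 stayed called without the R337Q line, where Itgae stood at -0.15, Klrg1 at -0.26, Tigit at -0.15, Prdm1 at -0.32, Gpr83 at -0.21, Tnfsf8 at 0.55 and Il21 at 3.06, and the Treg identity list lost its call (adjusted p = 0.654), and 61 genes passed with the block, among which Ankrd55 and Il1rl1 did not. Without R337Q replicate 1 or 2 the count was 31 or 25, and without WT GFP replicate 1, 4 or 5 it was 171, 30 or 53.

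In reTreg the means called 1 gene each, Slc35d1 in males (-0.86 ± 0.16, adjusted p = 0.0211, lower in 8 of 8 lines) and Ly6a in females (-0.58 ± 0.11, adjusted p = 0.0146, lower in 5 of 6 lines), and neither passed without the R337Q line (-0.70 and -0.31). Here too the lines of a background share WT libraries. Cell cycle, type I interferon, glycolysis, oxidative phosphorylation and ribosomal protein lists were higher in males, and in females the cell cycle list was higher and ribosomal proteins and B cell markers lower. All of these were lost with an estimated correlation, where the smallest adjusted p was 0.276. Male and female means were then compared over the 6 lines carried by both sexes. No gene differed by edgeR's test in aTreg (709 at an unadjusted p under 0.05; 1 by DESeq2) or in reTreg (777; 0). Treg identity genes and B cell markers were higher and Th1 and cell cycle genes lower in the male than in the female effect in aTreg (adjusted p = 0.0841, 0.342, 0.0841 and 0.581 with an estimated correlation), and without R337Q the Treg identity (0.233) and cell cycle calls were lost. Oxidative phosphorylation and ribosomal protein lists were higher in the male effect in reTreg (0.841 and 0.697 with an estimated correlation). By line, R337Q aTreg differed between the sexes in 135 genes (106 higher and 29 lower in the male effect; 320 with the library block), R51Q aTreg in 6 (2 with the block), R309Q aTreg in 2 and R51Q reTreg in 2 (1 with the block).

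**Figure D3:**
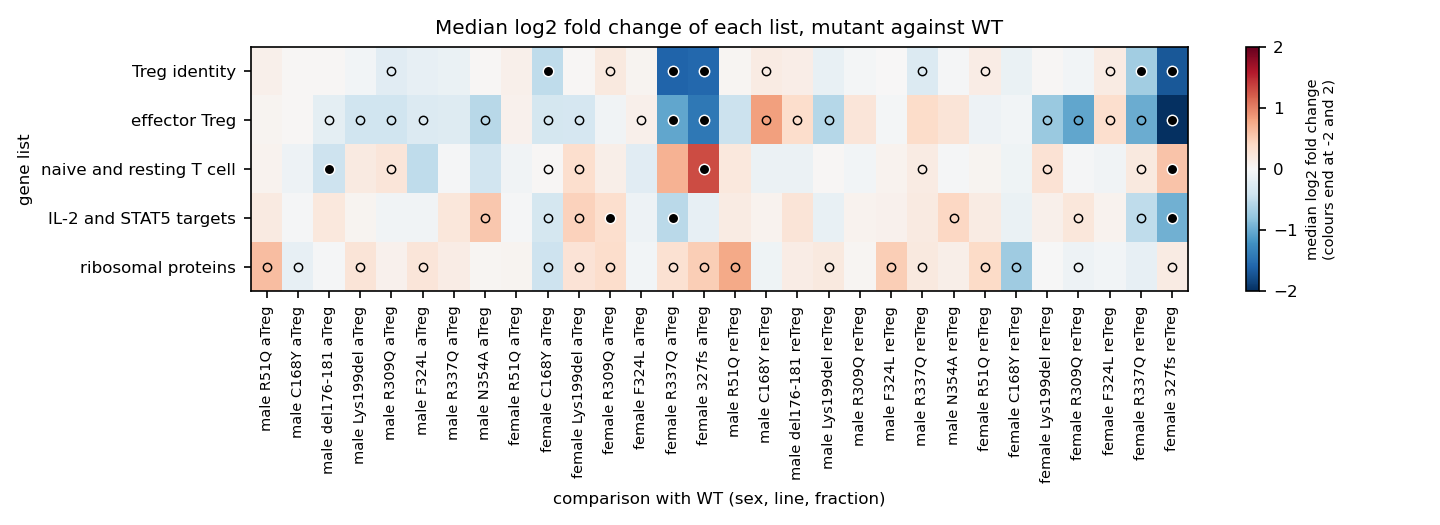
Median log2 fold change against WT of 5 gene lists in each comparison of a line with WT, where red is higher and blue lower in the mutant and colours end at -2 and 2. Filled dots mark lists called with an estimated correlation and open dots lists called only with the preset one; Treg identity is darkest in female R337Q aTreg and in female 327fs.

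The gates on GFP and CD25 ask which cells of the 327fs line carry the changes, with GFP reporting transcription of Foxp3. Because the gates select on GFP and CD25, levels of Foxp3 and Il2ra in them are partly set by the sort. In female GFP-positive CD25lo cells (3 against 2 libraries) Foxp3 stood at 503 ± 21.6 CPM against 1250 ± 95.9 CPM (-1.31 ± 0.13), Klrg1 was at least 481-fold lower, and Tigit (-5.13 ± 0.50) and F13a1 (-4.64 ± 1.07) fell. Ggt5 (4.88 ± 0.54), Gbp11 (3.49 ± 0.74) and the vitamin D receptor Vdr (3.40 ± 0.65) rose. Of the lists 13 of 23 Treg identity and 18 of 23 effector Treg genes fell and 7 of 15 naive and resting genes rose. GFP-positive CD25-negative cells (3 against 1) could only be set against a lone WT library, assumed to vary like the other groups, so that a feature of that library cannot be told from an effect of the line. Against it Penk (-6.18 ± 0.94), Tigit (-5.78 ± 0.54), Ctla4 (-2.08 ± 0.17) and Ikzf2 (-2.03 ± 0.15) fell, Ggt5 (3.85 ± 0.57), Myo6 (3.39 ± 0.65) and Lypd6b (3.38 ± 0.97) rose, and the WT to mutant ratio of Klrg1 was 1590 (counting interval 284 to 62913). On the same assumption 22 of 23 effector Treg and 10 of 15 cell cycle genes were called lower and 20 of 20 ribosomal protein genes higher. The counts were 648 (253 higher, 395 lower) and 1259 (389 higher, 870 lower), the first 400 without mutant replicate 3. In GFP-negative cells of the same females (3 against 1) Foxp3 was near the floor in both groups (3.08 ± 0.869 and 3.72 CPM) and 1 gene was called, again against a lone WT library, so the low count leaves open whether these cells differ.

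In GFP-positive cells of male 327fs mice, which have no WT allele, 2 libraries, 1 from each of 2 gates, were compared with 6 of WT. Both mutant libraries have the same title number and the WT libraries share theirs between the gates, so they can come from fewer mice than libraries, and the test treated them as independent. Foxp3 fell by 1.07 ± 0.12, Il2ra by 1.59 ± 0.22, the antiviral gene Oas1a by 7.13 ± 0.66 and the guanylate-binding protein Gbp2b by 6.78 ± 1.38, and the WT to mutant ratio of F13a1 was 161 (counting interval 28.8 to 6372). Lilr4b (10.34 ± 0.73), Epas1 (9.81 ± 0.36) and the type 2 cytokine Il4 (7.48 ± 0.48) rose. Of the lists 16 of 23 effector Treg, 6 of 7 Th2 and 9 of 12 glycolysis genes rose and 10 of 15 type I interferon response genes fell, all also with an estimated correlation, and 10 of 23 Treg identity genes fell (adjusted p = 0.106 with an estimated correlation). The labels of the GFP-negative male libraries disagree on the age of the mice, in the same way for mutant and WT. In these cells (2 against 3) the neutrophil granule genes Ngp and Ltf, without counts in WT, were at least 13283-fold and 7446-fold higher, and the ratio for S100a8 was 30862 (counting interval 8543 to 254851). All 9 myeloid and all 8 erythroid and platelet markers and 6 of 10 B cell markers rose, as did 21 of 23 effector Treg and 14 of 15 cell cycle genes, and 14 of 15 naive and resting genes fell. Il2ra (3.04 ± 0.31), Ctla4 (2.69 ± 0.19) and Ikzf2 (2.31 ± 0.14) rose and Arhgap29 fell by 4.77 ± 0.88, while the WT to mutant ratio was 112 for Ifit3b and 52.4 for Adh1. Foxp3 was low in both groups (7.85 ± 4.75 CPM in mutant and 11.7 ± 2.13 CPM in WT) and was called lower (-0.64 ± 0.23, adjusted p = 0.0368). The counts were 2496 (1392 higher, 1104 lower) and 5015 (2836 higher, 2179 lower), the second 2571 without mutant replicate 1.

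Male mutant Tconv (1 library each of C168Y, F324L, Lys199del, R309Q and R337Q) were compared with 5 WT Tconv. No gene passed edgeR's test (404 of 11334 at an unadjusted p under 0.05; 3 by DESeq2). Foxp3 was at 65.6 ± 51.4 CPM in the mutants and 63.7 ± 71.0 CPM in WT. Of the lists 6 were called and none with an estimated correlation, where the smallest adjusted p was 0.499. The effects of different lines were then correlated across genes, which are not independent replicates, for pairs of lines that share no WT library. Over 166 such pairs the median Pearson r was 0.0367, from -0.615 to 0.494. The same line in the 2 sexes had a median r of 0.106 in aTreg and 0.0874 in reTreg, and 0.149 and 0.142 with the library block. Female R337Q and female 327fs had an r of 0.458 in aTreg and 0.494 in reTreg, the latter the highest of all pairs, and 0.392 and 0.317 with the library block. Female R337Q and female Lys199del had an r of 0.465 in aTreg, and 0.323 with the block. Among pairs with shared WT libraries the median covariance was above the simulated value for lines without effect in female B6 reTreg (0.0618 against 0.0284) and male GFP aTreg (0.0360 against 0.0337), and below it in the other 6 sets. With the library block, for which no value was simulated, it was 0.0244 in female B6 reTreg and 0.0448 in male GFP aTreg, and it moved from 0.0331 to 0.0640 in male GFP reTreg. Single pairs departed from these medians without the block. In male B6 aTreg (simulated 0.0687) del176-181 and N354A had 0.145, R337Q and N354A 0.136, and del176-181 and R337Q 0.104. The other pairs of that set lay below the simulated value. In female GFP aTreg (simulated 0.0402) Lys199del and 327fs had 0.0964 and Lys199del and F324L 0.0455, with the other pairs below. The simulation used the dispersion trend of the whole fit, in which some groups mix library blocks, while male B6 libraries are all of block 1. The simulated value can thus be too high or too low for a set. The side on which a covariance lies therefore does not decide whether lines share an effect.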

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

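The tests of explanations given here were written after the results were seen, as were the splits of male R51Q, C168Y, Lys199del and R337Q aTreg and of female R51Q, C168Y and Lys199del aTreg. The other splits were written before. Differences between groups come from tests of the difference itself.

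Of 78 sets of values (Foxp3, Il2ra, Ctla4, Ikzf2, the total count and the number of genes detected) in groups of 4 to 10 libraries, 3 had a library far from the others, and chance gives about 1 in 20 such groups. Foxp3 stood at 603 CPM in female R309Q aTreg replicate 5 and at 1689 to 1896 CPM in the other 4 libraries. Ctla4 stood at 1111 CPM in replicate 1 of the same group and at 468 to 595 CPM in the others. Ikzf2 stood at 249 CPM in female R51Q reTreg replicate 2 of the GFP background and at 352 to 373 CPM in the others.

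The effects of lines differed from each other, by a joint test over lines, in 216 genes in male and 995 in female aTreg, and in 116 genes in male and 548 in female reTreg. With the library block the female reTreg count was 61. Between the sexes, the effect of a line differed in 135 genes for R337Q aTreg (320 with the block), in 6 for R51Q aTreg (2), in 2 for R309Q aTreg (2) and in 2 for R51Q reTreg (1). As lists, the male minus female effect differed in aTreg for Treg identity (adjusted p = 0.000168), Th1 (0.00121), cell cycle (0.0455) and B cell markers (0.0455), and in reTreg for oxidative phosphorylation (0.000814) and ribosomal proteins (7.39e-14), all by camera and none with an estimated correlation.

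Data outside the comparisons held signals too. In the library titled as female aTreg but labelled male, the Y-linked gene Ddx3y stood at 62.8 CPM, and in the matching reTreg library at 35.2 CPM, against 0 to 5.25 CPM in 92 libraries labelled female and a lowest value of 33.7 CPM in those labelled male. In the 2 male 327fs GFPlo CD25-positive libraries, which have no WT counterpart, Foxp3 had a mean of 281 CPM, against 9.31 to 13.3 CPM in the 3 male WT GFP-negative libraries, whose labels disagree on age. The gate on GFP partly sets this difference. Single male 327fs libraries of the GFPhi CD25-positive and GFP-positive CD25-negative gates stood at 629 and 425 CPM. Male WT GFPhi CD25-positive cells stood at 1231 ± 42.9 CPM.

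The first pattern weighed is the number of genes called in male R51Q aTreg and female C168Y reTreg. For R51Q, 38 genes stayed called in the same direction with the library block, which argues against the block as the whole cause. With block 3 left out 3975 genes were called, 700 of the 789 among them, but there the mutants are of block 2 and 3 of the 4 WT libraries of block 1. For the 751 genes that lost their call a median share of 0.727 of the fold change was left (quartiles 0.601 to 0.850), and 718 of the 789 genes went the same way within block 3 (2 against 2, median size 0.57) and 783 within block 2 (3 against a lone WT library, 1.03). The genes were picked from the same libraries, so how much of their change is due to the block stays open. For C168Y a median share of 0.402 was left, and its mutant libraries are all of block 1 while WT are of blocks 2 and 4, so line and block cannot be told apart. An effect of either mutation stays open.

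The second pattern is the low Foxp3 and Treg gene level in female R337Q aTreg. Genes over 8-fold higher in WT Treg than Tconv fell there by a median of 1.60 (-1.60, over 87 genes), as Foxp3-negative T cells in the sort could give, although the sort took CD25-positive cells. As the whole cause this is argued against by 10 of the 87 genes, which fell more than Foxp3 by a test of their difference within each library, among them Itgae (Holm adjusted p = 1.50e-08), Klrg1 (0.000541) and Ccr8 (0.0378). The library block is argued against too, since Foxp3 stood at -2.18 with it. In the same line's reTreg 78 of the 87 genes fell (median -0.79, 3 of them called) while Foxp3 stood at 0.35 ± 0.27, where Foxp3-negative cells would lower Foxp3 as well, though 1 of those 2 libraries was of low quality. In aTreg of hemizygous R337Q males the 87 genes had a median of -0.15 (5 called lower, 4 higher) with Foxp3 at -0.22 ± 0.26, so no such fall was seen where each cell carries the mutation. An effect of R337Q in heterozygous females stays open, and the 2 libraries are few.

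The third pattern is the 5015 genes called in male 327fs GFP-negative cells. All 9 myeloid markers were higher, which fits myeloid cells in the sort, although the gate required TCRb and CD4. Myeloid markers made up 2.41% and 0.595% of counts in the 2 mutant libraries against 0.00449% to 0.0193% in WT, and S100a8 stood at 10156 and 2230 CPM. T cell genes were lower in the same libraries. Trac stood at 222 and 484 CPM against 703 to 794 CPM in WT, Cd4 at 230 and 711 against 809 to 921, and Cd3e at 381 and 582 against 774 to 857. The marker share thus does not give the share of other cells. Myeloid cells as the whole cause are argued against by 21 effector Treg genes that were higher, of which some, such as S100a4 and Lgals1, are also expressed by myeloid cells. Activation of T cells in these mice stays open as an untested explanation.

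Other splits of the same libraries, which held neither the library block nor the title number fixed, were used to ask whether chance can be excluded. It can for the WT comparisons, where 1 of 100 splits, the real one, gave as many genes (Treg against Tconv 1628, highest other 92; male aTreg against reTreg 1379 and 64; female 2824 and 57). It can for female 327fs (1 of 56 in aTreg, 646 and 57, and 1 of 56 in reTreg, 294 and 17), which gave 801 and 300 genes with the library block. There no other split came near the real count. For female Lys199del aTreg (1 of 56, 17 and 8, and 16 with the library block) the margin was small. Leaving out single libraries moved its count from 1 to 68. For the male mean in aTreg (2 of 100, 26 and 41) another split called more genes. Over this many split tests such shares can arise by chance, so chance is not excluded for female Lys199del aTreg or for that mean. For female F324L reTreg (1 of 56, 8 and 0), female R51Q reTreg (3 of 100, 3 and 3) and female C168Y reTreg (1 of 100, 630 and 353) the real split parts the blocks unevenly and 0 genes passed with the block. Splits that ignore the blocks treat unlike libraries as alike there, so neither chance nor the blocks are excluded. Chance cannot be excluded for male R51Q aTreg (6 of 100, 788 and 2707, the highest following the blocks; 38 with the block), male R51Q reTreg (7 of 35, 160 and 746), male Lys199del aTreg (9 of 100, 2 and 769) and reTreg (17 of 35, 8 and 2987, the highest parting blocks 1 and 3), female C168Y aTreg (6 of 100, 11 and 717), female R309Q aTreg (31 of 100, 2 and 2591), the female mean in aTreg (7 of 100, 83 and 1013) and the means in reTreg (male 9 of 100, 1 and 5; female 12 of 100, 1 and 1311). Splits that call several times the real count point to a structure of the libraries such as the blocks. With no gene called, every split was as large: 100 of 100 for female R51Q aTreg (highest other 1), female R309Q reTreg (3186) and the sex differences (2 and 77), 56 of 56 for female F324L aTreg (0) and Lys199del reTreg (4), 35 of 35 for male F324L reTreg (22) and 99 of 99 for Tconv (31). The splits were too few for male R337Q aTreg (1 of 10, 103 and 0) and male C168Y aTreg (10 of 10, 0 and 0).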

How the results depend on the processing

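All values without library block 3, with the library block as a covariate, without the R337Q line and with the mouse as a replicate block in WT Treg against Tconv were chosen after seeing the data, and the other alternatives before the data were examined. Counts of genes are given wherever they moved by more than 1.5 times, with the count of the report in brackets, and the cause was not tested unless one is named. Among named genes called in either fit, 2 reversed their direction under the alternatives run. The call, and the direction of genes called, stayed the same in 796 of 811 values with DESeq2, 798 of 811 with RLE scaling, 726 of 767 with the library block and 596 of 659 with littermate WT. Genes not called could change sign, such as Foxp3 in female C168Y reTreg (0.19, and -0.36 with the library block). The 2 reversals were Cggbp1 in female R51Q reTreg, which stood at 0.45 with the B6-background libraries alone, and S100a8 in female C168Y aTreg, which stood at -0.73 without replicate 2 and at 8.82 without replicate 1. Foxp3 was called in 3 of the 30 line comparisons, and in 4 with WT pooled over backgrounds. The median r between effects of lines was 0.0367, and 0.0278 with the library block.

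With DESeq2 it was 18 for female 327fs GFPneg cells (1), 5 for the female reTreg mean of lines (1), 45 for the male aTreg mean of lines (26), 3 for the male reTreg mean of lines (1), 1 for the aTreg sex difference (0) and 3 for mutant Tconv (0). With DESeq2 the female aTreg count was 17 for C168Y (11), 1 for F324L (0), 71 for Lys199del (17), 35 for R309Q (2) and 1 for R51Q (0). With DESeq2 the female reTreg count was 5 for Lys199del (0), 9 for R309Q (0), 97 for R337Q (50) and 30 for R51Q (3). With DESeq2 the male aTreg count was 2 for C168Y (0), 3 for F324L (0), 8 for Lys199del (2), 69 for N354A (45), 1 for R309Q (0), 159 for R337Q (103), 1242 for R51Q (789) and 21 for del176-181 (5). With DESeq2 the male reTreg count was 1 for C168Y (0), 1 for F324L (0), 172 for Lys199del (8), 12 for N354A (2), 43 for R337Q (27), 414 for R51Q (160) and 3 for del176-181 (0). With RLE scaling the female reTreg count was 1 for Lys199del (0). With RLE scaling the female aTreg count was 4 for R309Q (2). With RLE scaling the male reTreg count was 49 for Lys199del (8) and 5 for N354A (2). With RLE scaling it was 2 for the male reTreg mean of lines (1). DESeq2's size factors moved the median of all genes by 0.10 in male Lys199del reTreg, and by less in the other comparisons.

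Without a gene filter more genes near the floor were tested. With no gene filter it was 135 for female 327fs GFPneg cells (1), 1681 for the female aTreg difference between lines (995), 1078 for the female reTreg difference between lines (548), 1764 for the female aTreg mean of lines (83), 359 for the female reTreg mean of lines (1), 859 for the male aTreg difference between lines (216), 550 for the male reTreg difference between lines (116) and 128 for the male aTreg mean of lines (26). With no gene filter it was 20 for the male reTreg mean of lines (1), 9 for the aTreg sex difference (0), 8 for the reTreg sex difference (0) and 6 for mutant Tconv (0). With no gene filter the female aTreg count was 134 for C168Y (11), 3 for F324L (0), 102 for Lys199del (17), 97 for R309Q (2) and 31 for R51Q (0). With no gene filter the female reTreg count was 58 for F324L (8), 13 for Lys199del (0), 63 for R309Q (0), 98 for R337Q (50) and 75 for R51Q (3). With no gene filter the male aTreg count was 17 for C168Y (0), 23 for F324L (0), 21 for Lys199del (2), 104 for N354A (45), 11 for R309Q (0) and 66 for del176-181 (5). With no gene filter the male reTreg count was 19 for C168Y (0), 17 for F324L (0), 32 for Lys199del (8), 24 for N354A (2), 2 for R309Q (0), 53 for R337Q (27), 282 for R51Q (160) and 20 for del176-181 (0). With the stricter gene filter the female reTreg count was 2 for Lys199del (0). With the stricter gene filter the female aTreg count was 10 for R309Q (2). With the stricter gene filter it was 55 for the female aTreg mean of lines (83). With the stricter gene filter the male reTreg count was 34 for Lys199del (8), 6 for N354A (2) and 282 for R51Q (160).

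With WT pooled over backgrounds the female reTreg count was 456 for 327fs (294), 0 for C168Y (630), 86 for F324L (8), 1 for Lys199del (0), 78 for R337Q (50) and 0 for R51Q (3). With WT pooled over backgrounds the female aTreg count was 8 for Lys199del (17), 59 for R309Q (2), 1199 for R337Q (797) and 9 for R51Q (0). With WT pooled over backgrounds it was 2330 for the female aTreg difference between lines (995), 259 for the female reTreg difference between lines (548), 2 for the female reTreg mean of lines (1), 979 for the male aTreg difference between lines (216), 686 for the male reTreg difference between lines (116), 111 for the male aTreg mean of lines (26) and 20 for the male reTreg mean of lines (1). With WT pooled over backgrounds the male reTreg count was 19 for Lys199del (8), 18 for N354A (2), 106 for R337Q (27), 106 for R51Q (160) and 2 for del176-181 (0). With WT pooled over backgrounds the male aTreg count was 98 for N354A (45), 270 for R337Q (103), 1926 for R51Q (789) and 26 for del176-181 (5). With littermate WT alone the female aTreg count was 302 for 327fs (646), 0 for C168Y (11), 0 for Lys199del (17), 0 for R309Q (2) and 1415 for R337Q (797). With littermate WT alone the female reTreg count was 111 for 327fs (294), 83 for R337Q (50) and 1 for R51Q (3). With littermate WT alone it was 220 for the female aTreg difference between lines (995), 9 for the female reTreg difference between lines (548), 0 for the female reTreg mean of lines (1), 56 for the male aTreg difference between lines (216), 15 for the male reTreg difference between lines (116), 0 for the male aTreg mean of lines (26), 3 for the male reTreg mean of lines (1) and 2 for the reTreg sex difference (0). With littermate WT alone the male aTreg count was 1 for Lys199del (2), 36 for R337Q (103) and 92 for R51Q (789). With littermate WT alone the male reTreg count was 5 for Lys199del (8), 4 for R337Q (27) and 90 for R51Q (160).

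For female R51Q, 5 genes passed in aTreg with the mean of both backgrounds (0), 118 genes passed in aTreg with the B6-background libraries alone (0) and 1 genes passed in reTreg with the mean of both backgrounds (3). With low-quality libraries left out the female reTreg count was 20 for R337Q (50). With low-quality libraries left out it was 2 for the female reTreg mean of lines (1). With low-quality libraries left out the male reTreg count was 0 for Lys199del (8), 7 for N354A (2) and 254 for R51Q (160).

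With library blocks the female aTreg count was 0 for C168Y (11), 10 for R309Q (2) and 1326 for R337Q (797). With library blocks the female reTreg count was 0 for C168Y (630), 0 for F324L (8), 2 for Lys199del (0), 130 for R337Q (50) and 0 for R51Q (3). With library blocks it was 61 for the female reTreg difference between lines (548), 2 for the female reTreg mean of lines (1), 51 for the male aTreg mean of lines (26) and 2 for the male reTreg mean of lines (1). With library blocks the male aTreg count was 12 for Lys199del (2), 72 for N354A (45), 167 for R337Q (103), 38 for R51Q (789) and 16 for del176-181 (5). With library blocks the male reTreg count was 73 for Lys199del (8), 12 for N354A (2), 42 for R337Q (27) and 65 for R51Q (160). With library block 3 left out the female aTreg count was 24 for C168Y (11), 65 for Lys199del (17), 25 for R309Q (2) and 1323 for R337Q (797). With library block 3 left out the female reTreg count was 1419 for C168Y (630), 25 for F324L (8), 5 for Lys199del (0), 108 for R337Q (50) and 43 for R51Q (3). With library block 3 left out it was 1975 for the female aTreg difference between lines (995), 1426 for the female reTreg difference between lines (548), 187 for the female aTreg mean of lines (83), 4 for the female reTreg mean of lines (1), 2490 for WT Treg against Tconv (1627), 2227 for male WT aTreg against reTreg (1379), 1202 for the male aTreg difference between lines (216) and 555 for the male reTreg difference between lines (116). With library block 3 left out it was 0 for the male reTreg mean of lines (1). With library block 3 left out the male reTreg count was 15 for N354A (2), 47 for R337Q (27) and 1836 for R51Q (160). With library block 3 left out the male aTreg count was 174 for R337Q (103), 3975 for R51Q (789) and 16 for del176-181 (5). With the title format the female aTreg count was 2 for C168Y (11) and 6 for R309Q (2). With the title format the female reTreg count was 159 for C168Y (630), 0 for F324L (8), 2 for Lys199del (0), 90 for R337Q (50) and 0 for R51Q (3). With the title format it was 585 for the female aTreg difference between lines (995), 106 for the female reTreg difference between lines (548), 53 for the female aTreg mean of lines (83), 2 for the female reTreg mean of lines (1), 191 for the male reTreg difference between lines (116) and 45 for the male aTreg mean of lines (26). With the title format the male aTreg count was 6 for Lys199del (2), 41 for R51Q (789) and 13 for del176-181 (5). With the title format the male reTreg count was 25 for Lys199del (8), 9 for N354A (2) and 528 for R51Q (160).

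Without the R337Q line, whose libraries enter each mean, 0 genes passed for the female aTreg mean of lines (83), 0 genes passed for the female reTreg mean of lines (1), 1 genes passed for the male aTreg mean of lines (26) and 0 genes passed for the male reTreg mean of lines (1). Of the 30 gene list calls over 6 contrasts 5 held with an estimated correlation.

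Title numbers are shared between groups without a label that says why. Over 30 comparisons, 23 of which had at least 3 pairs, the correlations of same-numbered libraries ran from -0.575 to 0.501 and were all above 0.1 only in male Lys199del aTreg and reTreg, so the numbers can mark pairs there and not in the others. With the title number as replicate block the female reTreg count was 1 for F324L (8) and 0 for R51Q (3). With the title number as replicate block it was 54 for the female aTreg mean of lines (83) and 3 for the female reTreg mean of lines (1). With the title number as replicate block the male reTreg count was 2 for Lys199del (8). With the title number as replicate block the male aTreg count was 475 for R51Q (789) and 8 for del176-181 (5). The mouse label of WT animals as a replicate block moved no count by more than 1.5 times.

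Leaving out each library in turn, in groups of 2 to 5, gave ranges of the number of genes called. In female aTreg the range was 378 to 615 for 327fs (646), 1 to 8 for C168Y (11), 1 to 68 for Lys199del (17), 3 to 31 for R309Q (2) and 181 to 214 for R337Q (797). It was 0 to 1 for female 327fs GFPneg cells (1), 400 to 908 for female 327fs CD25lo cells (648), 1015 to 1067 for female 327fs CD25neg cells (1259), 529 to 1265 for the female aTreg difference between lines (995), 320 to 650 for the female reTreg difference between lines (548), 25 to 171 for the female aTreg mean of lines (83), 0 to 2 for the female reTreg mean of lines (1) and 2267 to 2333 for male 327fs GFP-positive cells (2496). It was 2571 to 5109 for male 327fs GFPneg cells (5015), 164 to 268 for the male aTreg difference between lines (216), 55 to 790 for the male reTreg difference between lines (116), 11 to 29 for the male aTreg mean of lines (26), 0 to 2 for the male reTreg mean of lines (1) and 1301 to 1424 for WT Treg against Tconv (1627). In female reTreg the range was 170 to 291 for 327fs (294), 125 to 162 for C168Y (630), 0 to 20 for F324L (8), 0 to 2 for R309Q (0), 0 to 14 for R337Q (50) and 0 to 21 for R51Q (3). In male reTreg the range was 0 to 1 for C168Y (0), 0 to 6 for F324L (0), 0 to 1593 for Lys199del (8), 0 to 1 for N354A (2), 7 to 15 for R337Q (27) and 2 to 543 for R51Q (160). In male aTreg the range was 0 to 4 for del176-181 (5), 1 to 5 for Lys199del (2), 2 to 33 for N354A (45), 56 to 65 for R337Q (103) and 21 to 1794 for R51Q (789). In the other 11 results with refits the count stayed as it was.

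The share of changes recovered was measured on simulated data, which hold no differences between library blocks. There 67% of 2-fold and 98% of 4-fold changes were recovered in the comparison of male R337Q aTreg, 39% and 90% in that of male R51Q aTreg, and 49% and 95% in that of female 327fs CD25lo cells.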

Other observations

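In 3 libraries the labels disagreed, and they entered no comparison. The library titled as WT Tconv whose genotype reads R51Q had 49.4 CPM of Foxp3. Those titled as heterozygous female aTreg and reTreg but labelled male had 1153 and 1533 CPM of Foxp3 and 3.16 and 0.696 CPM of Xist, against a lowest Xist of 251 CPM in libraries labelled female and a highest of 34.2 CPM in those labelled male.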
